A study of Saccharolobus islandicus REY15A with 4 samples.

How the data were processed

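RNA was sequenced from 4 cultures of Saccharolobus islandicus REY15A strains, E233S1 and its tfb3 deletion, each with and without 2 µM NQO for 6 h at 78 °C, 1 library per group. Per the labels' protocols, ribosomal RNA was removed and the libraries were made to keep the strand. Reads were aligned with Bowtie2 2.2.3, per the submitters' processing notes. The tool that counted reads, whether it used the strand, and the genome build were not given in the sources used here. The authors deposited a table of RPKM values for 2629 genes with a length for each gene, per the file headers (RPKM scales reads by the gene's length and the library's reads). Of the lengths, 97.2% are multiples of 3, as most coding lengths are. No other column of sample values was found in the table (0 unused).

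The RPKM values keep enough digits for the reads to be recovered. Apart from the values given below, RPKM times length is a whole multiple of the value of 1 read, within a tolerance of 0.01 reads. The reads of each library were taken as the denominator that this value implies. All values were whole in the E233S1 libraries. In the untreated deletion library 14 values were not whole, and 1 of these genes was also not whole in the NQO-treated deletion library. Of the 14, 10 become whole with the length of the row before and 1 with that of the row after, so values seem to have been set against the wrong rows. These 14 genes were left out, a choice made after the table was examined, and 2615 genes remained. Keeping them as deposited is an added alternative. The recovered reads served only for depth, counting intervals and floors, since RPKM values are not counts and the libraries have no replicates.

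Gene IDs were matched to a reference table of assembly ASM18955v1. Of the IDs, 2511 matched and 118 did not, 2463 have an older locus tag (SiRe_) and 373 a symbol. Lengths equal the reference in 2326 genes and differ in 185, and no build is named with the values, so coordinates are not given and the table was used for names and gene order. tfb3, the Orc1 proteins, rad50 and the Dpo2 operon are named from their locus tags as background.

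With 1 library per group there is no replicate check, no test and no p-value across genes. The result of each comparison is the log2 ratio of RPKM + 1 per gene, for genes with at least 10 RPKM in the higher of the libraries compared (any of the 4 for the difference of responses), and the count of genes at least 2-fold higher or lower. The 5 comparisons are NQO against untreated in each strain, the deletion strain against E233S1 without and with NQO, and the difference of the NQO responses. Single ratios are RPKM ratios with exact 95% Clopper-Pearson limits of the recovered reads. Where a library had 0 reads the ratio is a bound against a floor of 3 reads in that library. The genes named are, by a rule set before the data were examined, label checks (tfb3, pyrE, pyrF, lacS), the 12 highest and 12 lowest ratios of NQO in E233S1, 8 and 8 in the deletion strain and between the untreated strains, 5 and 5 between the treated strains, 10 and 10 of the difference, and up to 4 members per list with the largest change of at least 2-fold. Other list members are named where a group is described, and SiRe_0016, SiRe_1431, SiRe_0002, SiRe_0062, segC and alba1 were named after their values were seen.

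Gene lists were planned by product text, which the reference table lacks. They were therefore rewritten as 21 lists by symbol and locus tag after the symbols were seen and before any ratio was computed. A list's median is given as its percentile among 10000 random lists of the same size, matched on mean expression in 10 bins. It is a description of these libraries, for lists with at least 3 members. Random lists are drawn gene by gene, so adjacent genes that change together count as separate members. Alternatives set before the data were examined were pseudocounts of 0.1 and 10 RPKM, no minimum, a minimum of 50 RPKM, thresholds of 1.5-fold and 4-fold, 5 bins, and 4 scalings (median of ratios, equal sums, the top 1% of genes left out, quantile normalization). The planned list definitions and the genes kept as deposited were added later.

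Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data for the comparison of NQO with untreated in E233S1. With 2375 genes tested, a library spread of 0.16 (log2) and the real depths, 62% of genes changed exactly 2-fold were called, 98% at 3-fold and 100% at 4-fold and 8-fold, with 6 calls among 2175 unchanged genes. All simulated reads were recovered. Of 100 lists of 8 unchanged genes, 3 fell outside the middle 95% of random lists.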

Results

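Transcript levels were measured by RNA sequencing in the hyperthermophilic archaeon Saccharolobus islandicus REY15A. The cultures were of E233S1, a genetic host strain derived from it, and of a strain that lacks tfb3, the gene of a paralog of the general transcription factor B. Cultures at 78 °C were sampled 6 h after addition of 4-nitroquinoline 1-oxide (NQO, 2 µM), a DNA-damaging agent, or after the same time without it. NQO was added at an optical density of 0.20. Each of the 4 groups is 1 library, so none of the differences below has a replicate check. By their RPKM denominators the libraries hold 5290365 reads (E233S1 untreated), 5116238 (E233S1 with NQO), 5184258 (deletion strain untreated) and 4199432 (deletion strain with NQO). At this depth 3 reads on a gene of 1 kb correspond to between 0.567 and 0.714 RPKM. Ranges in brackets are exact 95% Clopper-Pearson intervals of a ratio of RPKM values. They cover counting error only and compare these libraries, not the conditions. "Rose", "fell" and "changed" stand for a log2 ratio of RPKM + 1 of at least 1 in size. Low-expressed genes change less on that scale than in RPKM.

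The tfb3 gene (SiRe_1717) was read first, as a check of the labels. It stood at 14.7 RPKM in untreated E233S1 and 451 RPKM in E233S1 with NQO. In the deletion strain it had 2 reads without NQO (0.752 RPKM) and 4 reads with it (1.86 RPKM). The untreated deletion library was thus 19.6-fold lower than untreated E233S1 (5.08 to 167), and the NQO-treated one 243-fold lower than NQO-treated E233S1 (94.7 to 894). Both go with the labels. The uracil synthesis gene pyrE (SiRe_1392) was at 33.8, 19.6, 26.2 and 42.1 RPKM in the order of libraries above. No reading of the labels was drawn from pyrE. The other marker genes of the host planned as label checks, pyrF and lacS, were not analysed here.

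The first comparison asks which transcripts changed under NQO in the strain with tfb3. Among the fixed lists the highest median was that of the genes of the ups pili, UV-inducible pili by which cells aggregate, and of the Ced system for DNA import. All 8 measured genes of that list rose, with a median log2 ratio of 4.99, above all 10000 random lists matched on expression. The pilin gene upsA (SiRe_1881) went from 915 to 35107 RPKM, 38.4-fold (36.8 to 40.0). SiRe_1879, which lies between upsX and upsF, rose 45.2-fold (41.8 to 48.9), and upsB (SiRe_1882) rose 44.9-fold (29.7 to 71.1). In the Ced system, cedA1 (SiRe_1316) went from 692 to 21616 RPKM, cedA (SiRe_1317) from 268 to 8668 RPKM and cedB (SiRe_1857) from 91.8 to 2678 RPKM. tfb3 itself rose 30.6-fold (22.4 to 43.1).

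In all, 141 of the 2385 genes tested rose and 175 fell in E233S1 with NQO, and 24 rose at least 16-fold. Those 24 genes held 0.265% of the reads in untreated E233S1 and 8.70% with NQO. Beside ups and Ced genes the highest ratios were in SiRe_0020 at 61.5-fold (46.5 to 83.1), SiRe_0269 at 45.01-fold (37.7 to 54.1), SiRe_0137 at 44.4-fold (37.8 to 52.5) and SiRe_1715 at 40.6-fold (37.2 to 44.5). SiRe_0670 rose 40.1-fold (34.9 to 46.1), SiRe_0187 35.9-fold (30.2 to 43.0), SiRe_2100, which also has the symbol cedA, 34.1-fold (31.2 to 37.4) and SiRe_0936 33.5-fold (28.3 to 39.9). The reference table gave these genes no name apart from SiRe_2100.

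Of 12 genes of DNA repair and recombination, 5 rose and 1 fell, and their median log2 ratio of 0.40 lay at the 99.9th percentile of random lists. With the list definition first planned (9 genes) the median was 1.27. The 4 adjacent genes of the end-resection machinery rose together, and the percentile counts each of them separately. They are mre11 (3.45-fold, 3.18 to 3.75), nurA (3.46-fold, 2.91 to 4.13), the helicase gene herA (3.33-fold, 3.16 to 3.50) and SiRe_0062, listed as rad50, with a log2 ratio of 1.504. The recombinase gene radA rose 2.42-fold (2.35 to 2.48). Of the pair of hjc genes, which encode Holliday junction resolvases, SiRe_0930 fell 3.07-fold (2.38 to 4.01), while SiRe_1431 had a log2 ratio of 0.42. Among 9 replication genes the origin-binding proteins moved apart. SiRe_1231 (Orc1-2) rose 4.56-fold (4.22 to 4.93), SiRe_1740 (Orc1-1) fell 3.18-fold (2.88 to 3.51) and SiRe_0002 (Orc1-3) had a log2 ratio of -0.44. The 3 genes SiRe_0614, SiRe_0615 and SiRe_0616, known as the operon of the DNA polymerase Dpo2, rose 21.1-fold (18.4 to 24.4), 26.9-fold (24.8 to 29.1) and 25.4-fold (18.1 to 36.7).

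The genes of cell division fell. Of 8 measured, 7 fell, with a median log2 ratio of -1.88, below all random lists. The division proteins of this archaeon (Cdv) are relatives of the eukaryotic ESCRT machinery. The 2 cdvB1/B2 genes went from 9895 to 1150 RPKM (SiRe_1550, 8.61-fold lower, 8.32 to 8.91) and from 15112 to 2120 RPKM (SiRe_1200, 7.13-fold lower, 6.96 to 7.31). The ratios of cdvB and cdvC were 4.12-fold lower (3.85 to 4.41) and 4.02-fold lower (3.80 to 4.26). Only segC stayed within 2-fold, and clsN (-1.03) came to -0.95 with the median of all genes at 0. Of 8 chromatin and topology genes, 4 fell, and the median log2 ratio was -1.17, at the 0.02nd percentile. Without the most abundant 1% of genes, which leaves 5 of the 8, it was -0.35 and no longer outside random lists. cren7, which encodes a small DNA-bending chromatin protein, fell 9.14-fold (8.32 to 10.1). The 2 ssh7b genes, for Sul7-type chromatin proteins, fell 6.39-fold (SiRe_2648) and 4.16-fold (SiRe_0668), and the reverse gyrase gene SiRe_1124 fell 4.57-fold (4.38 to 4.77). The 2 ssh7b genes are close relatives, and how reads were shared between them is uncertain. The abundant chromatin gene alba1 had a log2 ratio of 0.27. The lowest ratios of all were in SiRe_0367, which went from 19 reads to 0 (at least 6.12-fold lower), SiRe_0266 (12.9-fold, 9.72 to 17.3), SiRe_0124 (13.2-fold, 9.72 to 18.4), SiRe_0267 (11.6-fold, 10.9 to 12.4) and csa3 (SiRe_0764), a CRISPR regulator, which went from 68 reads to 4. SiRe_2610, SiRe_1949, SiRe_1172 and SiRe_1890 were also among the 12 lowest, between 6.82-fold and 8.49-fold lower.

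**Figure D1:**
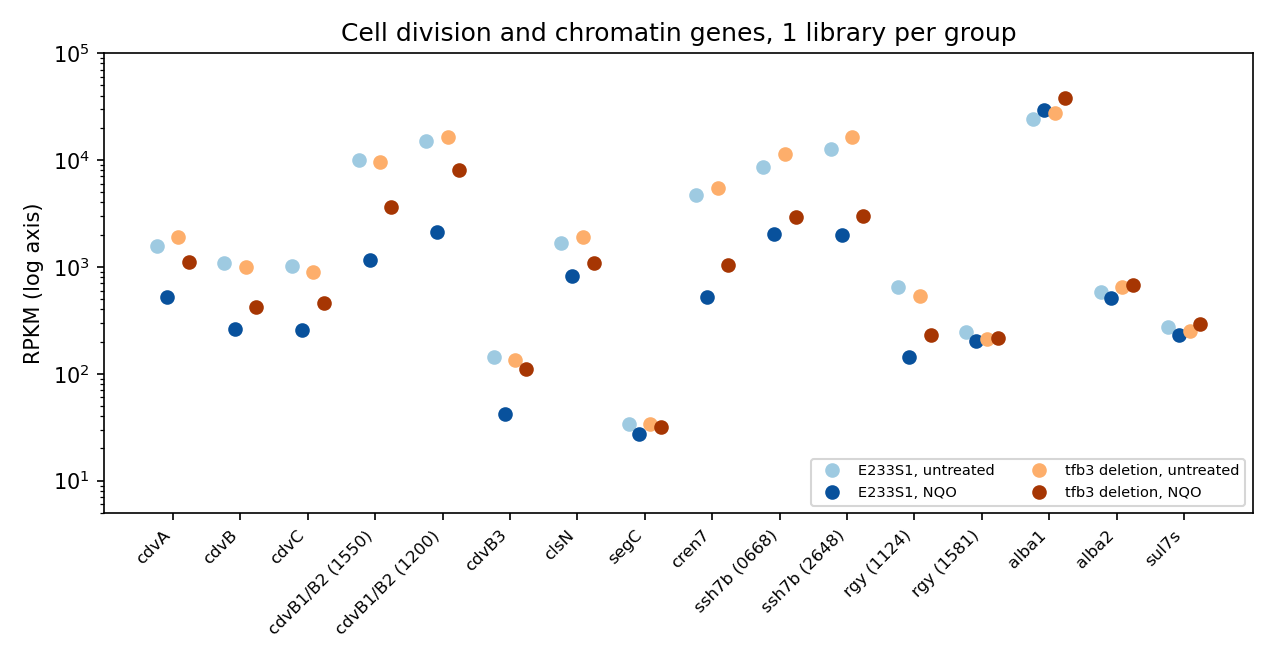
RPKM (log axis) of each cell division and chromatin gene in the 4 libraries, 1 point per library. The 2 cdvB1/B2 genes, cren7 and the 2 ssh7b genes sit lower in both NQO-treated libraries, and the cdvB1/B2 genes lowest in E233S1 (1150 and 2120 RPKM), while alba1 is lowest in untreated E233S1, at 24149 RPKM.

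Of the 16 other lists, 8 had no changed member in E233S1. These were 9 ribosomal protein genes, 10 chaperone and proteolysis genes, 10 purine synthesis genes, 17 genes of histidine, tryptophan and aromatic synthesis, 12 of sugar uptake and sugar polymers, 17 of tRNA and rRNA processing, 9 transposase genes and 5 of the basal transcription machinery. Of 26 CRISPR-Cas genes 4 rose and 3 fell. cas1 (SiRe_0761) rose 11.6-fold (8.21 to 16.9) and the cas4 gene SiRe_1994 rose 7.77-fold (7.30 to 8.27). In nucleotide synthesis 2 of 14 genes fell, dcd 3.54-fold (3.24 to 3.86) and thyX, a thymidylate synthase gene, 2.05-fold (1.84 to 2.27). A lone member changed in each of the remaining groups. These were dps of the antioxidant and metal storage genes (2.54-fold higher, 2.31 to 2.80), soxL2 of the respiration genes (3.50-fold higher, 3.25 to 3.78), argH of lysine, arginine and branched-chain synthesis (2.35-fold higher, 1.94 to 2.86), cobA of cobalamin and haem synthesis (3.91-fold higher, 2.14 to 7.64), acs of carbon metabolism (2.28-fold lower, 2.10 to 2.47) and metG of the tRNA synthetases and translation factors (2.13-fold lower, 1.72 to 2.66). With a pseudocount of 10 RPKM thyX, argH, cobA, metG and 4 of the 7 changed CRISPR-Cas genes (cas2, SiRe_0763, SiRe_0892 and cbp1) came under 2-fold. By their medians, some of the 16 lists also lay outside random lists. The antioxidant and metal storage list had a median log2 ratio of 0.38 at the 99.3rd percentile. This was close to the repair list (0.40, 99.9th percentile). The histidine, tryptophan and aromatic list had 0.20 at the 97.9th percentile. The rest of the 16 lay inside random lists.

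The same treatment was then compared in the strain without tfb3. All 8 ups and Ced genes had a smaller log2 ratio there than in E233S1. upsA went from 17.1 to 157 RPKM, and cedA1 from 221 to 316 RPKM. Of the 6 members with at least 10 RPKM, 4 rose, and the median log2 ratio was 1.27, still above all random lists. The members that rose, of those 6, were upsA (9.14-fold, 6.55 to 13.05), SiRe_1879 (6.30-fold, 3.83 to 10.9), cedB (2.79-fold, 2.41 to 3.24) and upsX (2.29-fold, 1.75 to 3.03). Below 10 RPKM, upsB went from 1 to 10 reads (12.3-fold, 1.76 to 536) and upsF from 18 to 51 reads (3.50-fold, 2.01 to 6.36), and with no minimum the median of all 8 was 1.45. With the median of all genes at 0 upsX came under 2-fold, at a log2 ratio of 0.96. SiRe_0670 went from 0 to 11 reads, which is at least 4.53-fold. The genes SiRe_0614 to SiRe_0616 behaved otherwise. They rose 10.6-fold (9.75 to 11.5), 10.5-fold (10.1 to 11.01) and 10.6-fold (8.88 to 12.8). With NQO they stood above E233S1 (2843 against 2003 RPKM for SiRe_0615), but by less than 2-fold. Their log2 ratios to E233S1 were 0.61, 0.51 and 0.69, where the median of all genes was 0.34. Their NQO responses were smaller than in E233S1, with log2 differences of -0.99, -1.34 and -1.17. SiRe_1231 rose 3.42-fold (3.20 to 3.66).

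Of the 12 repair genes 4 rose without tfb3, with a list median of 0.69 at the 99.95th percentile, and 0.83 with the list first planned. Which strain had the higher median thus depends on the list, and this was not tested. The median of the genes' differences between strains was 0.15, and 0.12 with the list first planned. These lay at the 20.5th and 18.2nd percentiles of random lists. The genes that rose were mre11 (2.85-fold, 2.60 to 3.14), nurA (2.76-fold, 2.33 to 3.29), herA (2.73-fold, 2.58 to 2.88) and radA (2.63-fold, 2.56 to 2.69). Of the cell division genes 3 of 8 fell, with a list median of -0.87, below all random lists. Under the alternatives the median lay between -0.86 (pseudocount of 10 RPKM) and -1.02 (median of all genes at 0). SiRe_1550 fell 2.59-fold (2.53 to 2.65), cdvB 2.34-fold (2.201 to 2.49) and SiRe_1200 2.06-fold (2.03 to 2.09), which came to a log2 ratio of -0.67 after quantile normalization. The same 4 chromatin genes fell as in E233S1, with a list median of -0.58, which became -0.073 and no longer lay outside random lists without the most abundant genes. cren7 fell 5.24-fold (4.87 to 5.65), the ssh7b genes 5.53-fold (SiRe_2648) and 3.89-fold (SiRe_0668) and SiRe_1124 2.33-fold (2.24 to 2.42). lrs14 (SiRe_1948), which encodes an abundant DNA-binding regulator, fell 4.54-fold (4.39 to 4.69), against 6.39-fold in E233S1, and its neighbour SiRe_1949 fell 4.31-fold (3.90 to 4.78). csa3 went from 80 reads to 2. The general transcription factor gene tfe rose 2.39-fold (1.99 to 2.87). SiRe_0828, SiRe_0829 and SiRe_2008 fell 4.71-fold, 7.16-fold and 4.34-fold in this strain and were within 2-fold in E233S1. SIRE_RS07480, SiRe_2409 and SiRe_2306 were among the highest ratios, on no more than 23 reads each. In total 115 of 2384 genes rose and 67 fell, and 1 gene (SIRE_RS07480, from 0 to 13 reads) passed 16-fold on the RPKM + 1 scale (at least 5.35-fold by its reads). cmr5, cbsB and a transposase gene (SIRE_RS12785) were the other members of fixed lists to change here without a change in E233S1, and cbsB came under 2-fold (0.78) with a pseudocount of 10 RPKM. The median log2 ratio of all genes was 0.15, against -0.08 in E233S1. The split moved with the scaling, to 76 higher and 104 lower when that median was set to 0, 86 and 95 without the most abundant genes and 86 and 98 after quantile normalization.

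**Figure D2:**
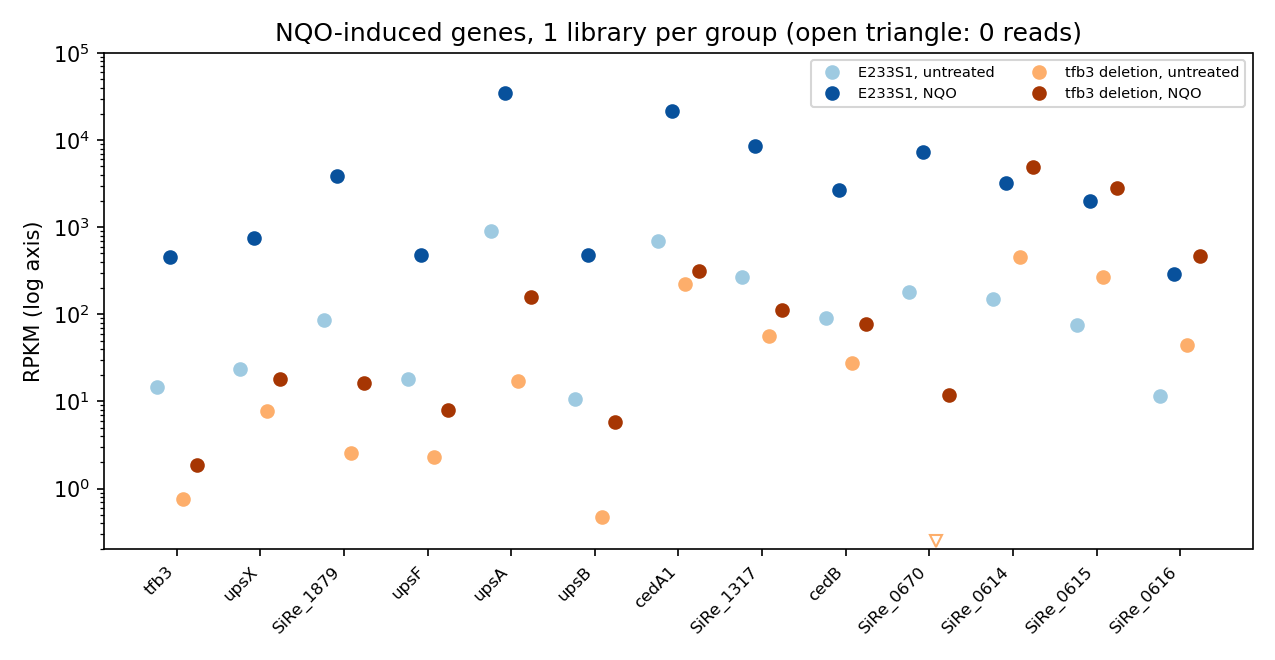
RPKM (log axis) of tfb3, the ups and Ced genes, SiRe_0670 and the genes SiRe_0614 to SiRe_0616 in the 4 libraries, 1 point per library. NQO-treated E233S1 is highest for tfb3, the ups and Ced genes and SiRe_0670 (35107 RPKM for upsA), and the NQO-treated deletion strain is highest for SiRe_0614 to SiRe_0616 (2843 RPKM for SiRe_0615).

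The strains were also compared without NQO. The ups and Ced genes were lower in the deletion strain before any treatment. All 8 were at least 2-fold lower, with a median log2 ratio of -2.38, below all random lists. With a pseudocount of 10 RPKM the median was -1.51, and upsB (-0.98) and upsX (-0.91) came under 2-fold. upsA was 53.4-fold lower (39.1 to 74.9), SiRe_1879 33.0-fold lower (21.0 to 55.2), upsF 7.95-fold lower (4.86 to 13.8) and cedA1 3.13-fold lower (2.73 to 3.59). SiRe_2100 was 32.0-fold lower (19.2 to 57.6), SiRe_0269 24.7-fold lower (10.3 to 77.4) and SiRe_1957 15.3-fold lower (13.4 to 17.5). SiRe_0670 and SiRe_0020 had 211 and 50 reads in E233S1 and 0 in the deletion strain, at least 68.9-fold and 16.3-fold lower. Of the 24 genes that rose at least 16-fold in E233S1, 18 were at least 2-fold lower in the untreated deletion strain. Among the 141 genes that rose in E233S1, 19 were lower here, tfb3 itself included, and 16 were higher, where independent lists would share 2.66 and 2.54. The comparisons share the untreated E233S1 library, whose noise works against the first overlap and towards the second. In 100 draws of unchanged libraries the second had a mean of 0.65, and part of its excess may come from the sharing.

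Few other genes separated the untreated strains. Of 2371 genes, 54 were higher and 45 lower in the deletion strain. Outside the ups and Ced genes, only dps and a transposase gene changed among list members. dps came to a log2 ratio of 0.98 with the median of all genes at 0, and the transposase gene to 0.90 with a pseudocount of 10 RPKM. The 9 transposase genes had a median log2 ratio of 0.62 at the 99.4th percentile, with 1 higher (SiRe_0886, from 19 to 53 reads). SiRe_0418, at 4754 RPKM in E233S1, was 16.5-fold lower (15.99 to 17.0), and it stayed 10.7-fold lower (10.3 to 11.1) with NQO. Higher in the deletion strain were SiRe_0615 (3.62-fold, 3.32 to 3.95), SiRe_0616 (3.85-fold, 2.63 to 5.76), SiRe_0828 (3.36-fold, 2.31 to 5.002), SiRe_0831 (3.43-fold, 2.46 to 4.86) and dps, for a ferritin-like protein that binds DNA (2.14-fold, 1.93 to 2.36). SiRe_0331, SiRe_2308, SIRE_RS02395 and SiRe_0076 were also higher, with at most 47 reads in the deletion strain. Of the 54 higher genes, 16 remained with a minimum of 50 RPKM and 15 with a pseudocount of 10 RPKM. The median of all genes was 0.10, and the split became 38 higher and 49 lower with that median at 0, and 32 and 44 after quantile normalization.

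Under NQO the difference between the strains was widest in the same genes. All 8 ups and Ced genes were lower in the deletion strain, by a median log2 ratio of -6.11. SiRe_0670 was 610-fold lower (341 to 1222), SiRe_1879 237-fold lower (194 to 292), SiRe_2100 229-fold lower (177 to 301), upsA 224-fold lower (200 to 252) and SiRe_0269 214-fold lower (140 to 347). The NQO-treated deletion strain was higher for SiRe_0266 (14.5-fold, 10.9 to 19.6) and SiRe_0267 (12.6-fold, 11.8 to 13.4), and, on at most 31 reads, for SiRe_2416, SiRe_0076 and SiRe_2259. Of the 8 cell division genes 4 were higher, with a list median of 0.97, above all random lists. SiRe_1200 was 3.77-fold higher (3.67 to 3.87), SiRe_1550 3.19-fold (3.07 to 3.31), cdvB3 2.62-fold (2.08 to 3.31) and cdvA 2.11-fold (2.00 to 2.24). The list median was 0.63 with the median of all genes at 0, and 0.63 without the most abundant genes. Orc1-1 (SiRe_1740), hjc (SiRe_0930) and dcd, which fell in E233S1, were 2.57-fold, 2.67-fold and 2.31-fold higher in the deletion strain. With the median of all genes at 0, cdvA and dcd came under 2-fold, at log2 ratios of 0.74 and 0.87. Overall counts were 128 higher and 87 lower of 2407 genes. The median of all genes was 0.34 here, the largest shift of the 5 comparisons. With it at 0 the split was 45 higher and 122 lower, without the most abundant genes 72 and 94, and after quantile normalization 58 and 110.

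The last comparison takes the difference between the NQO responses, the log2 ratio in the deletion strain minus that in E233S1. It was -3.31 at the median of the ups and Ced genes, all 8 of which had a smaller log2 ratio without tfb3. For upsB, with 1 and 10 reads in the deletion strain, the interval there (1.76 to 536) includes the 44.9-fold of E233S1. The lowest values were in SiRe_0426 (-5.07), SiRe_0137 (-5.03), SiRe_0936 (-4.53), cedA1 (-4.45), the deleted tfb3 (-4.14), SiRe_2101 (-4.06), SiRe_0671 (-4.05), SiRe_0589 (-4.04), SiRe_0015 (-4.04) and cedA (SiRe_1317, -4.03). SiRe_0426 went from 21.0 to 625 RPKM in E233S1 and from 14.1 to 11.7 RPKM in the deletion strain. Among list members, the cas4 gene SiRe_1994 (-2.86) and soxL2 (-2.29) rose in E233S1 and stayed within 2-fold without tfb3. cas1 (-3.98) also rose in E233S1 and was below 10 RPKM in both libraries of the deletion strain. The highest values were in SiRe_0266 (3.39) and SiRe_0267 (3.03), and in SIRE_RS07480, SiRe_0367 and SIRE_RS04055, each with 0 reads in 1 of the libraries. SiRe_1806 (2.42) and SiRe_2259 (2.46) also fell in E233S1 and stayed within 2-fold in the deletion strain. The cell division list had a median difference of 0.94, above all random lists, with 4 of 8 genes past 2-fold, of which cdvC came to 0.84 with the median of all genes at 0. The repair list had a median of 0.15 at the 20.5th percentile, but this turned to -0.08 with the median of all genes at 0. Of 2423 genes, 127 had a higher and 99 a lower log2 ratio in the deletion strain. With the median of all genes (0.23) set to 0 these were 72 and 127, and after quantile normalization 83 and 117.

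**Figure D3:**
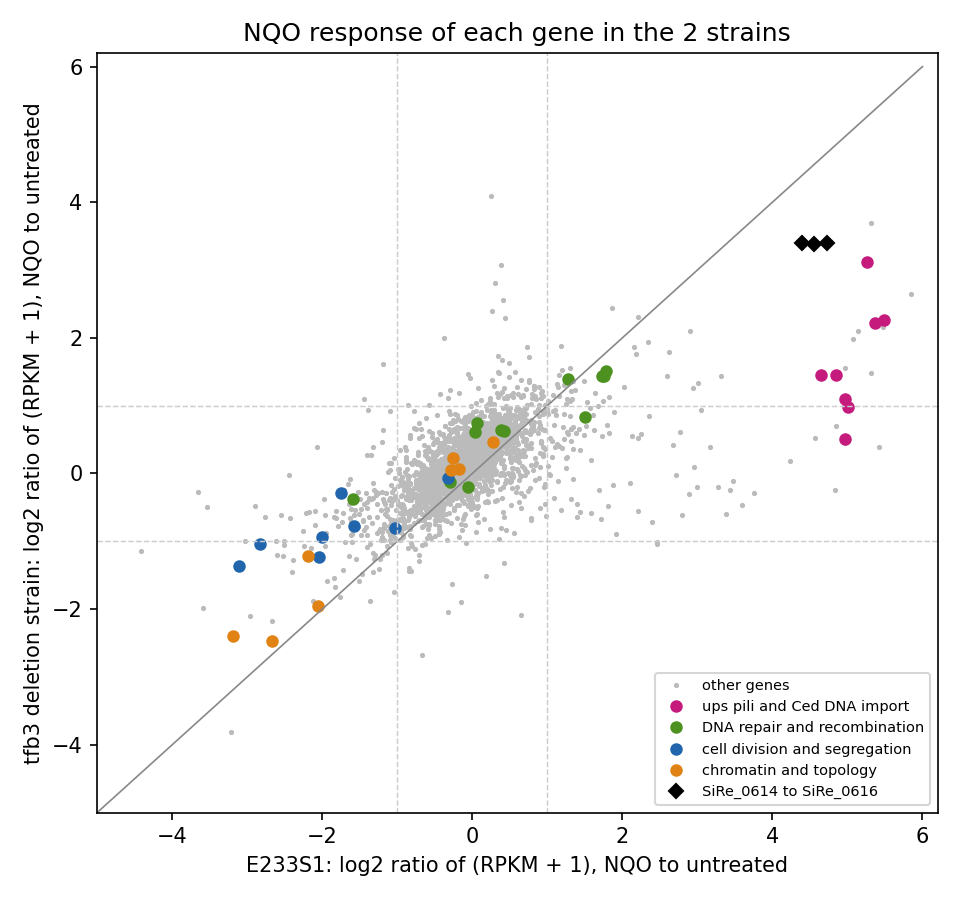
Each point is a gene, with the log2 ratio of RPKM + 1 (NQO to untreated) in E233S1 on the horizontal axis and in the deletion strain on the vertical axis. Dashed lines mark 2-fold and the solid line equal ratios. The ups and Ced genes lie far to the right, at a median of 4.99. On the vertical axis these 8 genes lie between 0.51 and 3.12, at a median of 1.45. Of the 12 repair genes, 11 lie within 2-fold of the line.

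Across the 2423 genes the responses of the strains went together, with Pearson's r of 0.597 and Spearman's rho of 0.633. Genes are not independent replicates, and the ratios share no library. Of the 141 genes that rose in E233S1, 41 also rose in the deletion strain, where independent lists would share 6.69. A further 74 stayed within 2-fold there, and 25 were below 10 RPKM in both libraries of that strain. The median log2 ratio of the 141 genes was 1.73 in E233S1 and 0.68 in the deletion strain. Of the 175 genes that fell, 47 also fell without tfb3, against 4.84 for independent lists, and 125 stayed within 2-fold. Their medians were -1.40 and -0.71. Genes chosen by their ratio in E233S1 tend to have a larger median there by that choice alone. Chosen in the deletion strain instead, the 115 genes that rose had medians of 1.27 there and 0.79 in E233S1. The 67 genes that fell there had medians of -1.26 there and -1.37 in E233S1. These overlaps and medians are at the main scaling and were not recomputed at the others. With the median of all genes at 0, the counts in the deletion strain were 76 higher and 104 lower. The 24 genes that rose at least 16-fold had a median of 4.97 in E233S1 and 1.52 in the deletion strain. Of the 19 of them with at least 10 RPKM in that strain, 13 passed 2-fold on the RPKM + 1 scale. On that scale SiRe_0614 to SiRe_0616, upsA and SiRe_0670 also passed 8-fold, where the reads of SiRe_0670 give only a bound of 4.53-fold. Opposite changes were seen in 3 genes, SiRe_0016, SiRe_0493 and SiRe_2455, and in none of them with a pseudocount of 10 RPKM.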

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

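These 3 genes were picked out because their log2 ratios of NQO-treated to untreated had opposite signs in the 2 strains, each at least 1 in size; the difference was not tested, since each group is 1 library. No test of a cause was run in this part, and none was chosen after the result was seen.

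SiRe_0016 rose from 48.3 to 270 RPKM in E233S1 and fell from 36.9 to 17.4 RPKM in the deletion strain, log2 ratios of 2.46 and -1.04 and a difference of -3.50. SiRe_0493 went from 18.4 to 6.11 RPKM in E233S1 and from 6.03 to 14.1 RPKM in the deletion strain, on 28, 9, 9 and 17 reads, a difference of 2.55. Its ratio in the deletion strain, 2.33-fold, has a counting interval of 0.983 to 5.94, which includes no change. SiRe_2455 went from 55.0 to 23.6 RPKM in E233S1 and from 12.6 to 40.5 RPKM in the deletion strain, on 89, 37, 20 and 52 reads, a difference of 2.79. With a pseudocount of 10 RPKM none of the 3 kept both changes, as SiRe_0016 came to -0.78 in the deletion strain, SiRe_2455 to -0.95 in E233S1, and SiRe_0493 to -0.82 in E233S1 and 0.59 in the deletion strain. SiRe_0493 also came under 2-fold in the deletion strain with median of ratios (0.96), without the top 1% of genes (0.98) and with quantile normalization (0.79). A minimum of 50 RPKM left out all 3.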

How the results depend on the processing

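No test of a cause was chosen after the result was seen in this part; the alternatives were fixed before the files were opened, except that keeping the 14 genes as deposited and the list definitions first planned were added after seeing the data. No value of a named gene changed sign. The balance of higher to lower counts did turn with median of ratios in all 5 comparisons, to 162 and 161, 76 and 104, 38 and 49, 45 and 122, and 72 and 127. The repair list, inside random lists there, went from 0.29 to -0.05 between the treated strains and from 0.15 to -0.08 for the difference. With that scaling 3 medians below random lists also changed sign and stayed below them, the list histidine, tryptophan and aromatic synthesis (0.11 to -0.23) and the list tRNA and rRNA processing (0.13 to -0.20) between the treated strains, and the list carbon metabolism (0.00137 to -0.22) for the difference. With the definition first planned the repair list was 1.27 in E233S1 and 0.83 in the deletion strain, against 0.40 and 0.69. Of 105 list medians, 20 lay outside the middle 95% of random lists, and between 19 and 23 did under the alternatives. Of 167 values of named genes, 18 came under 2-fold with a pseudocount of 10 RPKM, with median of ratios 12, with equal sums 3, without the top 1% 7 and with quantile normalization 13. A minimum of 50 RPKM left out 41. No paired analysis was possible because each group is 1 library.

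The counts moved as follows, higher before lower. At 1.5-fold they were 292 and 427 for NQO in E233S1, 432 and 230 for NQO in the deletion strain, 180 and 90 between the untreated strains, 630 and 133 between the treated strains, and 458 and 186 for the difference. At 4-fold they were 59 and 37, 15 and 8, 1 and 23, 9 and 49, and 18 and 49, in that order. With a pseudocount of 10 RPKM NQO in the deletion strain gave 74 and 42, and the higher counts were 15 between untreated strains, 73 between treated strains and 69 for the difference. With no minimum the untreated strains gave 96 and 74. With a minimum of 50 RPKM they gave 16 and 26, and the higher counts were 75 for NQO in the deletion strain and 80 for the difference. With median of ratios NQO in the deletion strain gave 76 and 104, and the higher counts were 45 between treated strains and 72 for the difference. Without the top 1% the treated strains gave 72 higher. With quantile normalization the higher counts were 32 between untreated strains, 58 between treated strains and 83 for the difference. Fewer genes are counted at a higher threshold or minimum, or with a larger pseudocount, by construction. The scalings move the log2 ratios of all genes, by a median of -0.338 between the treated strains with median of ratios. No further cause was tested for them.

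The correlation of the NQO responses was 0.524 with no minimum and 0.640 with a minimum of 50 RPKM. The chromatin list lost its place outside random lists without the top 1% of genes, at -0.35 in E233S1 and -0.073 in the deletion strain, where by construction only 5 of its 8 members were left. With quantile normalization the cell division list of the untreated strains (-0.18) and the chromatin list of the treated strains (0.46) came to lie outside random lists, and the cause was not tested. Depth limits genes at few reads, since 3 reads on a gene of 1 kb are 0.714 RPKM in the shallowest library.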

Other observations

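All tests in this part were chosen only after the results were seen.

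Many genes that rose in E233S1 and much less without tfb3 form short runs of neighbours. Beside the ups run (SiRe_1878 to SiRe_1882) and the cedA1 pair (SiRe_1316 and SiRe_1317), these are SiRe_0014 to SiRe_0016, SiRe_0166 and SiRe_0167, SiRe_0425 to SiRe_0427, SiRe_0588 and SiRe_0589, SiRe_1956, SiRe_1957 and SiRe_1960, and SiRe_2099 to SiRe_2101. SiRe_0425 and SiRe_0014 had log2 ratios of 3.47 and 2.80 in E233S1 and -0.11 and -0.61 in the deletion strain.

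It was asked as a hypothesis whether this is more than chance. Of 46 genes at least 2-fold higher in E233S1 with a difference of -2 or lower, 23 had another such gene as direct neighbour, where 10000 random sets had a mean of 1.68 and an upper 95% limit of 6. Of 28 genes that rose in both strains with a difference under 2-fold, 5 had such a neighbour, against a random mean of 0.606 and an upper 95% limit of 4. Neighbours beyond chance were thus not particular to the genes that rose much less without tfb3, and the test was prompted by the runs it counts. A further hypothesis was that the genes that fell in E233S1 and less in the deletion strain lie near the induced ones. Of 63 such genes 7 lay within 3 genes of an induced gene, against a random mean of 4.4 and an upper 95% limit of 9, so no excess beyond chance was seen.

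The first pattern weighed is the rise left in the NQO-treated deletion strain, which could be carried over from the NQO-treated E233S1 culture. The 4 reads of tfb3 allow at most 1.05% of such material. For SiRe_0614 to SiRe_0616 the rise was at least 102% of the level in NQO-treated E233S1, which excludes it there. Of the other 20 genes at least 16-fold higher in E233S1, 7 lay outside the pooled share and 5 outside the best common one, which excludes it as the whole cause. A common share of 0.399% held the other 15 genes. Among these, the intervals of SiRe_0426, SiRe_0137, SiRe_0589, SiRe_1316, SiRe_0671 and SiRe_0936 include no rise (-1.77% to 0.792% for SiRe_0426). No rise was thus established in those genes. For the rest of the 15, carry-over and a response without tfb3 could not be told apart.

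The second pattern is the lower cren7 and ssh7b under NQO in both strains. Loss of short transcripts would lower other short genes too. The median of 14 others was 0.164 in the deletion strain (95% bootstrap interval from -0.316 to 0.434), which argues against a general loss there. In E233S1 the median was -0.423, where loss could not be told (95% bootstrap interval of the median from -1.59 to 0.264). Of the 14 genes, 2 fell at least 2-fold in both strains. No other gene was as short and as abundant, so the level asked of the 14 was lowered from 2942 to 294 RPKM. Reads moved between copies were excluded, as the summed Sul7-type genes had log2 ratios of -2.34 in E233S1 and -2.18 in the deletion strain, and so was a share taken up by induced genes, as the highest ratio was still -1.88 with 215 induced genes left out. A response to NQO and other differences between the cultures were not tested.

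The third pattern is the lower SiRe_0413 to SiRe_0418 in the deletion strain, graded from 2.59-fold at SiRe_0413 to 16.5-fold at SiRe_0418 without NQO. A shift of all 6 genes by a row was excluded. They missed the E233S1 levels of the rows before or after by a median log2 of at least 1.30, which is 5.58 times the library spread. With NQO a single gene came as close as 0.101 to a neighbouring row, and a shift of single values was not tested. The genes missed their own rows as well, with log2 ratios from -1.37 to -4.04 without NQO. The test thus does not show that each value is in its right row. A lowest count of 43 reads argued against loss of the genes from every cell. The limit set for a missing gene was 3 reads, which the deleted tfb3 itself passed with 4 reads under NQO. Whether reads of related sequences were counted on these genes was not tested. Loss of the whole block from most cells was excluded. The log2 ratios of the 6 genes ranged over at least 2.43 in each treatment, which is at least 5.77 times the error. Loss of only part of the block was not tested. Without NQO, SiRe_0413 to SiRe_0415 were 2.59-fold to 3.07-fold lower, and SiRe_0416 to SiRe_0418 7.24-fold to 16.5-fold lower. An effect of tfb3 and another change in the deletion strain could not be told apart, since that strain is 1 culture line here.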
